A study of Rattus norvegicus with 24 samples.

How the data were processed

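Messenger RNA from nasal epithelium and from circulating white blood cells of male Fischer rats was measured on Affymetrix arrays with biotin-labelled RNA. The white blood cells came from whole blood drawn into cell preparation tubes, per the labels. The authors deposited one normalised intensity per probe set and array, and the deposited intensity values were positive, right-skewed and on a linear scale. Partek is named in the submitters' processing notes, and its version and the methods of background correction, summarization and normalization are not given in the sources used here. The table held 29214 probe sets and 24 arrays, with 0 sample columns left unassigned. Arrays of a tissue and day had near-equal distributions, while the 7 day and 28 day arrays lay on different scales, so levels were not compared between days without that limit. The number of arrays, 3 per group, limits the precision.

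Groups were taken from the sample titles. The numbers of the replicates were checked for pairing by the correlation of residuals between same-numbered arrays. Among 12 pairs of control and exposed arrays the r ran from −0.348 to 0.247, and among 12 pairs of nose and blood arrays from −0.202 to 0.171, with no statement of pairing in the labels. In nose at 28 days the 3 pairs of control and exposed arrays had r of 0.154 to 0.247, each over 0.1. The numbers may pair these arrays, though r elsewhere reached a larger size below 0. The fit without the block was kept as planned, with the block as an alternative. Gene symbols came from the platform's gene table, in which 15310 probe sets carried 1 symbol (14506 distinct symbols), 323 carried several and 13581 were absent. Of those with 1 symbol 15279 had a gene identifier present in the reference gene table. The values of 198 probe sets repeated those of another probe set on every array. Adh5 shared its probe set with a second gene and was not analysed here.

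Values were put on the log2 scale with no further normalization. Probe sets with a mean at or above percentile 25 of the tissue were kept, 21910 in each tissue and 20096 in both. In R 4.3.3, limma 3.58.1 was fitted to the 12 arrays of a tissue with 4 group means (lmFit, contrasts.fit and eBayes with its default prior), and to all 24 arrays for the difference between tissues. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets kept, and the threshold was an adjusted p under 0.05. The comparisons were exposed against control at each day in each tissue, the difference of that effect between the days and between the tissues, and 28 day against 7 day controls.

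The gene lists, 34 in number with 1150 symbols as written, and the rule for named genes were fixed before the files were opened. Each list was tested with camera at a preset correlation of 0.01, with 1 probe set per gene (that of the highest mean in the tissue), a minimum of 5 measured members and Benjamini-Hochberg adjustment within the comparison. Named genes were the 10 with the largest rise and the 10 with the largest fall past the threshold in each exposure comparison, or the 10 with the smallest unadjusted p and a difference of at least 1.5-fold where fewer passed. To these were added the 4 members with the largest moderated statistic of each called list, the enzymes Aldh2, Esd, Cat, Aldh1a1 and Aldh3a1 in every exposure comparison, and the 3 largest differences in each direction in the other comparisons. Effects were correlated across probe sets by Pearson's r and Spearman's rho, with an exact permutation p over 400 relabellings of the exposure of arrays. Shared calls were tested with Fisher's exact test, two-sided.

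The settings varied were the filter on dim probe sets (none, or the median of the tissue), the scaling (quantile normalization within the tissue, or centring each array on its median), the prior (intensity trend and robust), array quality weights (in nose and across tissues their estimation stopped before it converged), a replicate block, the arrays in the fit (only those compared, or all 24), the threshold (adjusted p under 0.1, or unadjusted p under 0.005 with a 1.5-fold difference), the list test (estimated correlation, or fry), the probe sets of a gene (their mean), the correlation (rank, or moderated statistics) and each array left out in turn. The mean of the olfactory list and that of the platelet list as covariates were added after seeing the data. Splits of the arrays were fitted in the same way, at most 100 per comparison with the real one included and random seed 1. Figures were drawn with matplotlib 3.10.9.

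The fits were tested on simulated data in which 200 of the probe sets were changed. At 2-fold the share recovered was 88.1% for nose at 7 days, 89.6% for nose at 28 days, 88.1% for blood at 7 days and 92.5% for blood at 28 days. At 1.5-fold these shares were 59.7%, 49.3%, 55.2% and 53.7%. For the difference between days 62.7% were recovered at 2-fold in either tissue. False calls numbered 6, 10, 7 and 15 in the 4 exposure comparisons, among 169, 169, 168 and 178 calls. The simulated noise was independent between probe sets, with a spread shared by the groups of a tissue. These figures do not cover genes that move together or groups of unequal spread, such as 28 day control nose.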

Results

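The study set out to measure how inhaled formaldehyde, an irritant gas that reacts with the lining of the nose, changes gene expression at the site of contact and in circulating blood. Male Fischer rats breathed 2 ppm formaldehyde in nose-only tubes for 6 hours a day over 7 or 28 days, and control rats spent the same time in tubes with room air. Messenger RNA of the nasal epithelium, collected from the maxilloturbinate according to the labels, and of circulating white blood cells was measured on Affymetrix arrays. The 24 arrays formed 8 groups of tissue, day and exposure with 3 arrays each, and this number limits the precision. The labels do not state that each replicate is a separate animal, so the p-values measure only the spread between samples. MicroRNA levels were not analysed here. Differences between groups are given on the log2 scale with their standard error from limma, on 3 arrays per group unless stated otherwise, and every test was two-sided. Fap, Mt1, Aldh3a2, Thbs1 and Ndc80 fall outside the rule for named genes and were chosen after their values were seen.

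The first comparison asked which genes differed between exposed and control nose after 7 days. Olfactory receptor genes, which encode the odorant detectors of olfactory sensory neurons, held 9 of the 10 largest rises past the threshold. Or4e5 (gene 290056, probe set 10783366) stood at 10.11 ± 0.94 (SD, n = 3) in exposed nose and 5.21 ± 0.46 in control nose, a rise of 4.90 ± 0.56 with a limma adjusted p = 0.00132. Or4k15 rose by 4.85 ± 0.60, Or4a15 by 4.18 ± 0.39 and Or4a66 by 3.64 ± 0.29. Moxd2, which is not a receptor gene, rose by 4.32 ± 1.03 from a control level of 6.09, and its call ended in 4 of the 6 fits that left out an array (3.80 to 5.09). The control levels of the 4 receptor genes, 4.48 to 5.21, lay under the level of the filter on dim probe sets, 6.61, and are not shown to be above background, nor is that of Moxd2, so the sizes of these rises are uncertain. The 4 receptors were tested in 4, 3, 3 and 3 of the 6 fits that left out an array, since the filter drops them without most exposed arrays, and those fits say little about single exposed arrays. Of the 29 measured members of the list of olfactory neurons and sustentacular cells, 11 rose, 0 fell and 18 did not pass the test, and 20 rose when adjusted over the list alone. Ncam2, an adhesion molecule of olfactory axons, rose by 2.31 ± 0.29, and Rtp2, which helps odorant receptors reach the cell surface, rose by 1.10 ± 0.17. All 29 members had a difference above 0, with a median of 1.48, and camera called the list higher with an adjusted p = 4.19e-12. Its adjusted p = 0.402 with an estimated correlation. The mean of the list lay 1.36 to 1.73 above the control mean on the 3 exposed arrays and −0.76 to 0.48 from it on the 3 control arrays. Among 519 named olfactory receptor genes, a set formed after the values were seen, 286 rose and 1 fell, with a median difference of 1.01. Some of the 519 reach the filter only through the exposed arrays. With no filter on dim probe sets 566 of 1052 receptor genes rose and 1 fell, with a median of 0.94, where chance sharing with the 1447 of 14506 named genes that rose would give 105 (Fisher's exact test, p = 1.36e-318). Genes are not independent replicates in this test, and the set was formed because receptors led the rises. After quantile normalization 260 receptors rose and 0 fell, and after median centring 282 rose and 0 fell. The 453 class II receptor genes had a median difference of 1.09, with 281 higher, and the 66 class I receptor genes a median of 0.49, with 5 higher and 1 lower. At 28 days 0 receptors passed, with medians of 0.20 for class II and 0.27 for class I. The 28 day nasal arrays lay on a lower intensity scale, and low signal may hide effects on receptors near the filter there.

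**Figure D1:**
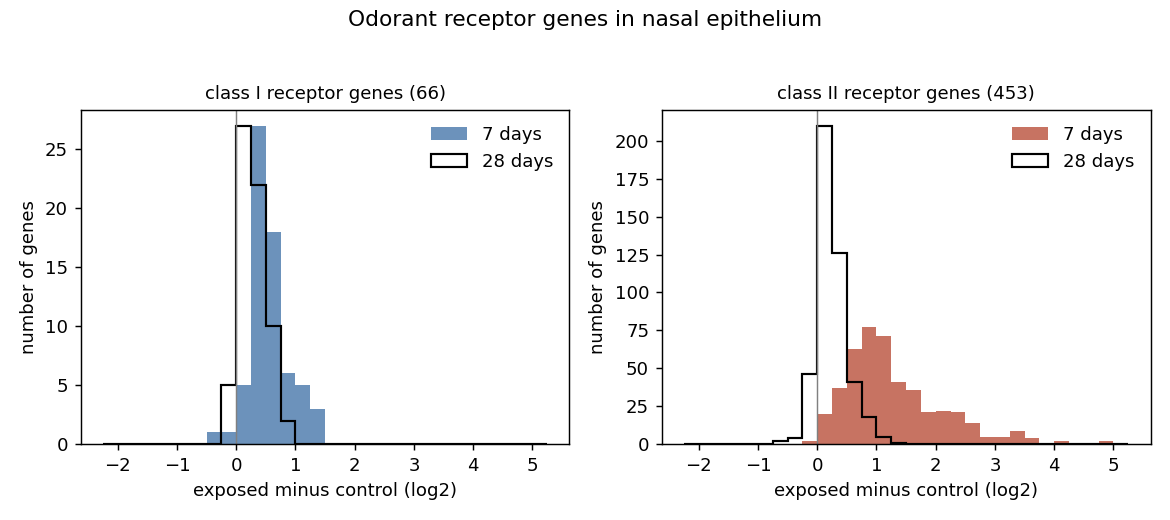
Histograms of the log2 difference (exposed minus control) of 66 class I and 453 class II olfactory receptor genes in nose at 7 and 28 days. At 7 days the class II genes center on a median of 1.09 and the class I genes on 0.49, and at 28 days on 0.20 and 0.27.

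Many of the listed genes of blood vessels were lower in exposed nose at 7 days. Of 25 members of the list of endothelium and pericytes 18 fell, 0 rose and 7 did not pass, and adjusted over the list alone 21 fell and 1 rose. Pecam1, a junction protein of endothelial cells, stood at 8.31 ± 0.30 (SD, n = 3) in exposed and 9.28 ± 0.20 in control nose. It fell by 0.97 ± 0.15, Erg by 0.71 ± 0.11, and Cdh5, the endothelial cadherin, by 0.61 ± 0.10. Among 27 members of the list of fibroblasts and extracellular matrix 11 fell, 1 rose (Fap) and 15 did not pass, with 16 lower and 1 higher adjusted over the list alone. The matrix metalloproteases Mmp2 and Mmp14 fell by 0.68 ± 0.09 and 0.66 ± 0.09. The list mean of endothelium lay 0.61 ± 0.16 (SD) below the control mean in the exposed group, with all 3 exposed arrays below all 3 control arrays. Over the 25 and 27 members, the medians were −0.68 and −0.29. The camera adjusted p was 7.61e-10 for endothelium and 1.29e-05 for fibroblasts. Their adjusted p was 0.373 and 0.323 with an estimated correlation.

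Some genes of immune cells were lower at the same time. Jchain, the joining chain of secreted antibodies, stood at 9.39 ± 0.57 (SD, n = 3) in exposed and 11.34 ± 0.06 in control nose and fell by 1.95 ± 0.38. In the list of B cells and plasma cells 8 of 17 members fell and 8 did not pass, and Ebf1, which is a factor of B cells and also of olfactory neurons, rose by 1.34 ± 0.30. The rise of Ebf1 was no longer past the threshold without control replicate 1 (1.18) or exposed replicate 1 (1.19). Adjusted over the list alone 15 fell and 1 rose. Among T cell genes 6 of 20 fell, 0 rose and 14 did not pass (8 fell adjusted over the list alone), and Il7r, a cytokine receptor of lymphocytes, fell by 0.98 ± 0.13. Of the 18 NK and cytotoxic cell genes 5 fell, 0 rose and 13 did not pass (6 fell adjusted over the list alone), with Klrk1, an activating receptor of NK cells, at −1.09 ± 0.18. For monocytes and macrophages 16 of 28 fell, 0 rose and 12 did not pass (21 fell and 1 rose adjusted over the list alone), among them Mpeg1, a pore-forming protein of macrophages, at −0.68. Of 12 genes of MHC class II presentation 9 fell, 0 rose and 3 did not pass (10 fell adjusted over the list alone), and RT1-Da fell by 0.74 ± 0.14. In the type 2 list 4 of 15 fell, 0 rose and 11 did not pass (9 fell adjusted over the list alone), with Ccl11, a chemokine that attracts eosinophils, at −1.16 ± 0.15. Among inflammatory cytokines and chemokines 6 of 25 fell, 0 rose and 19 did not pass (10 fell adjusted over the list alone), including Tnf at −0.87 ± 0.13 and the adhesion molecule Vcam1 at −0.75 ± 0.11. In the interferon list 10 of 37 fell and 25 did not pass, with Ifi47 at −0.92 ± 0.17, while Mx2, an antiviral GTPase, rose by 1.14 ± 0.17 and Cmpk2 by 0.71 ± 0.13 (21 fell and 2 rose adjusted over the list alone). Of 16 neutrophil genes Alox5ap and Hp fell, 0 rose and 14 did not pass (2 fell adjusted over the list alone). The erythroid list had 7 of 19 genes lower, 0 higher and 12 not past (8 fell adjusted over the list alone), with Alas2, an enzyme of heme synthesis, at −1.16 ± 0.20. In the platelet list 7 of 17 fell, 9 did not pass and Ppbp rose (9 fell and 1 rose adjusted over the list alone), but the call of Ppbp ended in 5 of the 6 fits that left out an array (0.34 to 0.52). Camera called each of these lists lower, with medians from −0.51 for MHC class II to −0.13 for erythroid cells. None held with an estimated correlation, with adjusted p values of 0.323 to 0.492. The call of the neutrophil list ended without exposed replicate 1 (median −0.095), and the median of the interferon list, −0.42, was then −0.22.

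Lists of stress responses and of other cell types were tested as well. Of 27 genes that respond to the transcription factor NRF2, 9 fell, Mt1 rose and 17 did not pass (10 fell and 1 rose adjusted over the list alone), with Gstp1, a glutathione transferase, at −0.96 ± 0.19. In the list of aldehyde and formaldehyde metabolism 7 of 25 fell, Aldh3a2 rose and 17 did not pass (9 fell and 1 rose adjusted over the list alone), with the oxidase Aox3 at −0.84 ± 0.16. Aldh1a1 fell by 0.98 ± 0.30, a call that ended without control replicate 1, 2 or 3 or without exposed replicate 1 (−0.59), with a range of −1.18 to −0.59 over the 6 fits that left out an array. The other enzymes of aldehyde removal named in advance did not pass, with Aldh2 at −0.08, Esd at −0.02, Cat at −0.45 and Aldh3a1 at −0.92. In the heat shock list 5 of 20 rose, 0 fell and 15 did not pass (6 rose and 1 fell adjusted over the list alone), among them the chaperone genes Hspa4l at 1.06 ± 0.20 and Hsp90aa1 at 0.49. For ciliated cells 8 of 38 rose, 2 fell and 28 did not pass (12 rose and 6 fell adjusted over the list alone), with the axonemal gene Ccdc40 at 0.68. Of 27 genes of basal cells and squamous differentiation Serpinb5, Gjb2 and Tp63 fell and 24 did not pass (0 adjusted over the list alone), and these calls ended in 4 (−1.45 to −0.68), 3 (−0.57 without exposed replicate 1) and 5 (−0.46 to −0.25) of the 6 fits that left out an array. In the p53 list Gdf15, Phlda3 and Fas fell of 19 (3 adjusted over the list alone), calls that ended in 4 (−0.94 to −0.50), 3 and 6 of these fits, and in the bone and cartilage list 3 of 30 fell (2 adjusted over the list alone). The 52 ribosomal protein genes had a median of −0.16 and 0 members past the threshold. Camera called the heat shock and ciliated lists higher and the other 6 lists of this paragraph lower, and with an estimated correlation the adjusted p values were 0.492 to 0.669. The median of the basal cell list, −0.38, was −0.24 without exposed replicate 1. The call of the ciliated list ended without control replicate 2 (median 0.012) or exposed replicate 2 (0.049), that of the p53 list without control replicate 1 (−0.13) or 3, and that of the bone list without control replicate 3 (−0.0088) or exposed replicate 1 (−0.076) or 2. Reported targets of let-7, a microRNA family, were not called, with 2 higher and 4 lower of 30 and a median of −0.06 (camera adjusted p = 0.579, and adjusted p = 0.709 with an estimated correlation). The other 11 lists not called had medians from −0.23 to 0.11, among them cell proliferation at 0.0050 and DNA crosslink and excision repair at −0.07.

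In total 1847 probe sets rose and 1717 fell in nose at 7 days among 21910 tested, and 820 of them differed at least 2-fold. The named genes among them numbered 1234 higher and 1208 lower. In all 98 genes named by rule that passed the threshold the 3 exposed and 3 control arrays did not overlap. Chance gives this for 10% of genes not chosen by their difference, so the count for genes chosen by passing adds no evidence. Camera called 22 lists, 3 higher and 19 lower, of which 17 were also called by fry, which tests only whether a list moved on balance one way, and 0 held in any comparison when the correlation was estimated. The total of 3564 became 802 without exposed replicate 1, 846 without control replicate 1 and 1608 without control replicate 3. It was 255, of which 233 were among the 3564, with the mean of the olfactory list as a covariate, an alternative chosen after seeing the data. Each exposed array lay above each control array in that mean, so this fit cannot tell the exposure from the list mean.

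**Figure D2:**
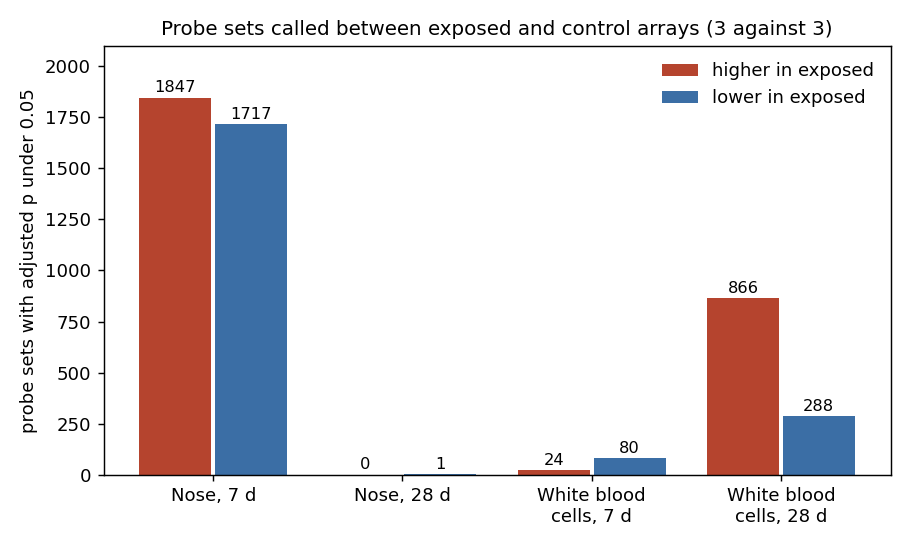
Bars give the number of probe sets higher or lower in exposed than in control samples at adjusted p under 0.05 for each tissue and day. The counts were 1847 and 1717 in nose at 7 days, 0 and 1 in nose at 28 days, 24 and 80 in blood at 7 days, and 866 and 288 in blood at 28 days.

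The same question was asked of the nose after 28 days. No named gene passed the threshold there. Clca1, a secreted product of mucous cells, stood at 5.94 ± 0.38 (SD, n = 3) in exposed and 9.83 ± 1.36 in control nose, a difference of −3.89 ± 0.63 (limma adjusted p = 0.0793). Its exposed level lay under the 6.61 of the filter, so the size of the difference is uncertain. The secreted protease inhibitor gene Slpi had a difference of −1.31 ± 0.21, the neuropeptide gene Calcb −1.71 ± 0.27, the macrophage gene Mpeg1 −0.83 ± 0.13 and the meiotic gene Dmc1 0.75 ± 0.11. Ccl2, which recruits monocytes, had −1.33 ± 0.28, and the squamous gene Sprr3 had −1.84 ± 0.57 with an exposed level, 6.54, under the filter too. The enzymes Aldh2, Esd, Cat, Aldh1a1 and Aldh3a1 had differences of 0.74, 0.0039, −0.011, 0.06 and −0.16, none past the threshold.

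The direction of gene lists could still be tested in nose at 28 days, and camera called 16 lists, 2 higher and 14 lower, with 0 members past the threshold in each. The list of olfactory neurons and sustentacular cells was higher with a median of 0.94, and the list of ciliated cells was higher with a median of 0.08. The lists of interferon response (−0.24), inflammatory cytokines and chemokines (−0.21), monocytes and macrophages (−0.20), fibroblasts and extracellular matrix (−0.17) and neutrophils (−0.29) were lower. Adjusted over the list alone, 9, 7, 6, 8 and 4 of their members fell. Basal cells and squamous differentiation (−0.43), mucous and secretory cells (−0.15), cell proliferation (−0.13), bone and cartilage (−0.14), MHC class II presentation (−0.14), B cells and plasma cells (−0.15), platelets (−0.09), NK and cytotoxic cells (−0.08) and endothelium (−0.09) were also called lower. None of the 16 calls held with fry or with an estimated correlation, where the adjusted p values were 0.536 to 0.736. Without control replicate 1 the number of called lists was 6. The calls of the lists of olfactory neurons (median 0.17), basal cells (−0.17), mucous cells, proliferation, bone, MHC class II, B cells, NK cells, platelets, ciliated cells and endothelium (0.025, the opposite sign) then ended. The median of the neutrophil list was then −0.16. Calls of the ciliated, endothelium, B cell, NK cell and platelet lists also ended without at least 1 other array. The mean of the olfactory list on that array was 7.41, against 9.43 and 9.63 on the other two control arrays and 9.52 to 9.92 on the exposed arrays. Reported let-7 targets had a median of 0.04 and were not called.

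By limma 1 probe set passed the threshold in nose at 28 days, against 3385 at an unadjusted p under 0.05, where chance gives 1095.5. It carried no gene name (probe set 10886599, named after its values were seen) and fell by 1.36 ± 0.13 (adjusted p = 0.00862), with all 3 exposed arrays below all 3 controls. The count was 1081 without control replicate 1, with Clca1 among the genes then past the threshold, 130 without control replicate 2, 3 without control replicate 3 and 0 without any one exposed replicate, and it was 42 after quantile normalization. With the replicate block it was 0, and the call of that probe set was lost.

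The third comparison asked whether the exposure effect in nose differed between the days, as the 28 day effect minus the 7 day effect. Olfactory receptors held most of the named genes past the threshold. Or4e5 had an interaction of −5.39 ± 0.79, Or4a15 of −4.15 ± 0.55 and Or4k15c of −3.44 ± 0.47, so their difference was lower at 28 than at 7 days. The sizes are uncertain, since the 7 day control levels of all 3 genes lay under the filter. At 28 days Or4e5 (5.86 in exposed and 6.34 in control nose) and Or4k15c (5.67 and 5.78) lay under its 6.61 in both groups. For them the interaction cannot tell a smaller effect at 28 days from low signal. Of 22 probe sets past the threshold, all lower, 12 had a gene name, and these were 11 olfactory receptors and Ndc80, a kinetochore gene, at −1.25 ± 0.14. Camera called 14 lists, of which fry called 0. The lists of endothelium and pericytes (0.50), circadian clock (0.46), MHC class II presentation (0.31), NRF2 (0.29), p53 targets (0.29), glucocorticoid response (0.24), B cells (0.22), erythroid cells (0.20), T cells (0.19), ribosomal proteins (0.14) and NK cells (0.13) had a higher effect at 28 days. Those of olfactory neurons (−0.57), cell proliferation (−0.19) and heat shock response (−0.061) had a lower one. The adjusted p values were 0.716 to 0.831 with an estimated correlation. Across 21910 probe sets the effects at 7 and 28 days correlated with Pearson's r = 0.462 (exact permutation p = 0.30) and Spearman's rho = 0.399 (exact permutation p = 0.24), and 62.0% had the same sign. The r was 0.0968 without 28 day control replicate 1 and 0.641 without 28 day control replicate 3. The arrays were relabelled in 400 ways, so the smallest possible p was 0.005, and the Benjamini-Hochberg adjusted p over the 4 correlations computed was 0.6. The interactions of Or4e5 (−5.91 to −4.83) and Or4k15c (−3.71 to −3.08) lost their call in 8 of the 10 fits without an array that tested them, and that of Or4a15, tested in only 4 of 12 such fits, ended in 3, without 7 day control replicate 2 (−3.95) or 3 or 28 day exposed replicate 1 (−3.78). Only the lists of endothelium, MHC class II, erythroid cells and circadian clock were called in every such fit, and the olfactory median ranged from −1.34 without 28 day control replicate 1 to −0.21 without 7 day control replicate 1. The heat shock median ranged from −0.14 to −0.011 and the glucocorticoid median from 0.090 to 0.37. Over the same fits the median was 0.19 to 0.44 for NRF2, 0.17 to 0.33 for p53 targets and −0.24 to −0.097 for cell proliferation. It was 0.082 to 0.22 for NK cells and 0.084 to 0.19 for ribosomal proteins. The count of 22 was 2648 without 28 day control replicate 1, of which 1369 were higher and 1279 lower. With the replicate block it was 82, and the calls of the NK and glucocorticoid lists were lost (camera adjusted p = 0.0515 for both). Quantile normalization left 1 probe set and array weights left 0.

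Control nose was also compared between the days, a comparison in which age, time in tubes and batch cannot be separated. The deposited levels lie on different scales, with array medians of 305 to 312 at 7 days and 163 to 172 at 28 days, and the median difference of all genes was −0.99. Clca1 (3.53 ± 0.63) and Or4a15 (2.15 ± 0.39) were higher at 28 days, and the apoptosis gene Pdcd4 (−2.43 ± 0.42) and Phf7 (−2.27 ± 0.13) were lower by more than that shift. Since the 7 day levels of Clca1 and Or4a15, 6.30 and 4.48, lay under the filter, the sizes of their rises are uncertain. Krt76, a keratin, had 1.69 ± 0.73, its control groups overlapped, and its call ended in 5 of the 6 fits that left out an array, with 0.58 without 28 day control replicate 1 and 2.62 without 28 day control replicate 2. Cabs1 had −2.56 ± 1.08 and was not past the threshold after either scaling or without 28 day control replicate 1, 2 or 3, and it had −0.86 without 7 day control replicate 1. In total 235 probe sets were higher and 19798 lower, 1.17% higher, while quantile normalization gave 3184 higher and 3333 lower and median centring 5092 higher and 3171 lower. Camera called the lists of basal cells (median −0.75), mucous cells (−0.81) and olfactory neurons (−0.96) higher than other genes although their medians and means were negative. Each had an adjusted p of 0.960 with an estimated correlation.

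The comparison of white blood cells after 7 days asked whether the exposure was seen away from the nose. Some genes of cytotoxic lymphocytes were higher. Gzmk (gene 29165, probe set 10821377), a granule protease of NK and T cells, stood at 11.69 ± 0.08 (SD, n = 3) in exposed and 10.72 ± 0.27 in control blood, a rise of 0.97 ± 0.15 with a limma adjusted p = 0.0313. Klrg1, a receptor of NK and T cells, rose by 0.95 ± 0.14, Gzma by 0.91 ± 0.16 and Gzmb by 0.70 ± 0.13. In the list of NK and cytotoxic cells these 4 of 32 members rose, 0 fell and 28 did not pass, and 23 rose when adjusted over the list alone. All 32 had a difference above 0, with a median of 0.51 (camera adjusted p = 6.92e-16, and adjusted p = 0.787 with an estimated correlation). The list mean was 0.47 to 0.54 above the control mean on the exposed arrays and −0.17 to 0.11 from it on the control arrays. Ogg1, a DNA glycosylase that removes oxidised guanine, rose by 0.63 ± 0.10, alone among 22 genes of DNA repair, of which 7 rose adjusted over the list alone.

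Blood at 7 days also had lower levels of some genes of red cell precursors. Sptb, a spectrin of the red cell membrane, stood at 9.77 ± 0.20 (SD, n = 3) in exposed and 11.37 ± 0.43 in control blood and fell by 1.60 ± 0.29. The membrane anchor Ank1 fell by 1.80 ± 0.33 and the mitochondrial iron carrier Slc25a37 by 1.28 ± 0.24. These 3 of 24 erythroid genes fell, 0 rose and 21 did not pass, and 16 fell when adjusted over the list alone. The median was −0.65 (camera adjusted p = 9.26e-16, and adjusted p = 0.787 with an estimated correlation). In the neutrophil list Ngp, a granule protein, fell by 1.75 ± 0.31 and 27 of 28 did not pass. The list of immediate early genes was called lower (median −0.14), with 0 members past the threshold and 3 lower adjusted over the list alone, and so were circadian clock (−0.10), MHC class II (−0.09), B cells (−0.08) and neutrophils (−0.25). The lists of heat shock response (0.24), ribosomal proteins (0.13), DNA repair (0.11) and oxidative phosphorylation (0.11) were called higher. Leaving out 1 array moved the medians of MHC class II (−0.20 to −0.013), B cells (−0.15 to −0.010), neutrophils (−0.43 to −0.072) and circadian clock (−0.13 to −0.058), and each of these calls ended without at least 1 array. For all 11 called lists fry called 0, and with an estimated correlation the adjusted p values were 0.787 to 0.998. Reported let-7 targets had a median of 0.03, and platelets, monocytes and T cells had medians of 0.02, 0.04 and 0.06, none called. The enzymes Aldh2 (−0.19), Esd (0.36), Cat (−0.50) and Aldh3a1 (−0.05) did not pass, and Aldh1a1 was removed by the filter on dim probe sets in blood.

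In blood at 7 days 24 probe sets rose and 80 fell of 21910, against 3316 at an unadjusted p under 0.05, and 13 of the 104 differed at least 2-fold. The arrays did not overlap in all 20 named genes that passed, a count set largely by that choice, as the 10% of chance holds for genes not so chosen. The count of 104 was 2 without control replicate 2 or exposed replicate 2, 3 without exposed replicate 3, 4 without control replicate 3 and 5 without exposed replicate 1, so each named gene lost its call in several of these fits. Only the calls of the NK, erythroid, immediate early and heat shock lists were past the threshold in every such fit, and the count was 463 from the 6 arrays of that day alone.

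**Figure D3:**
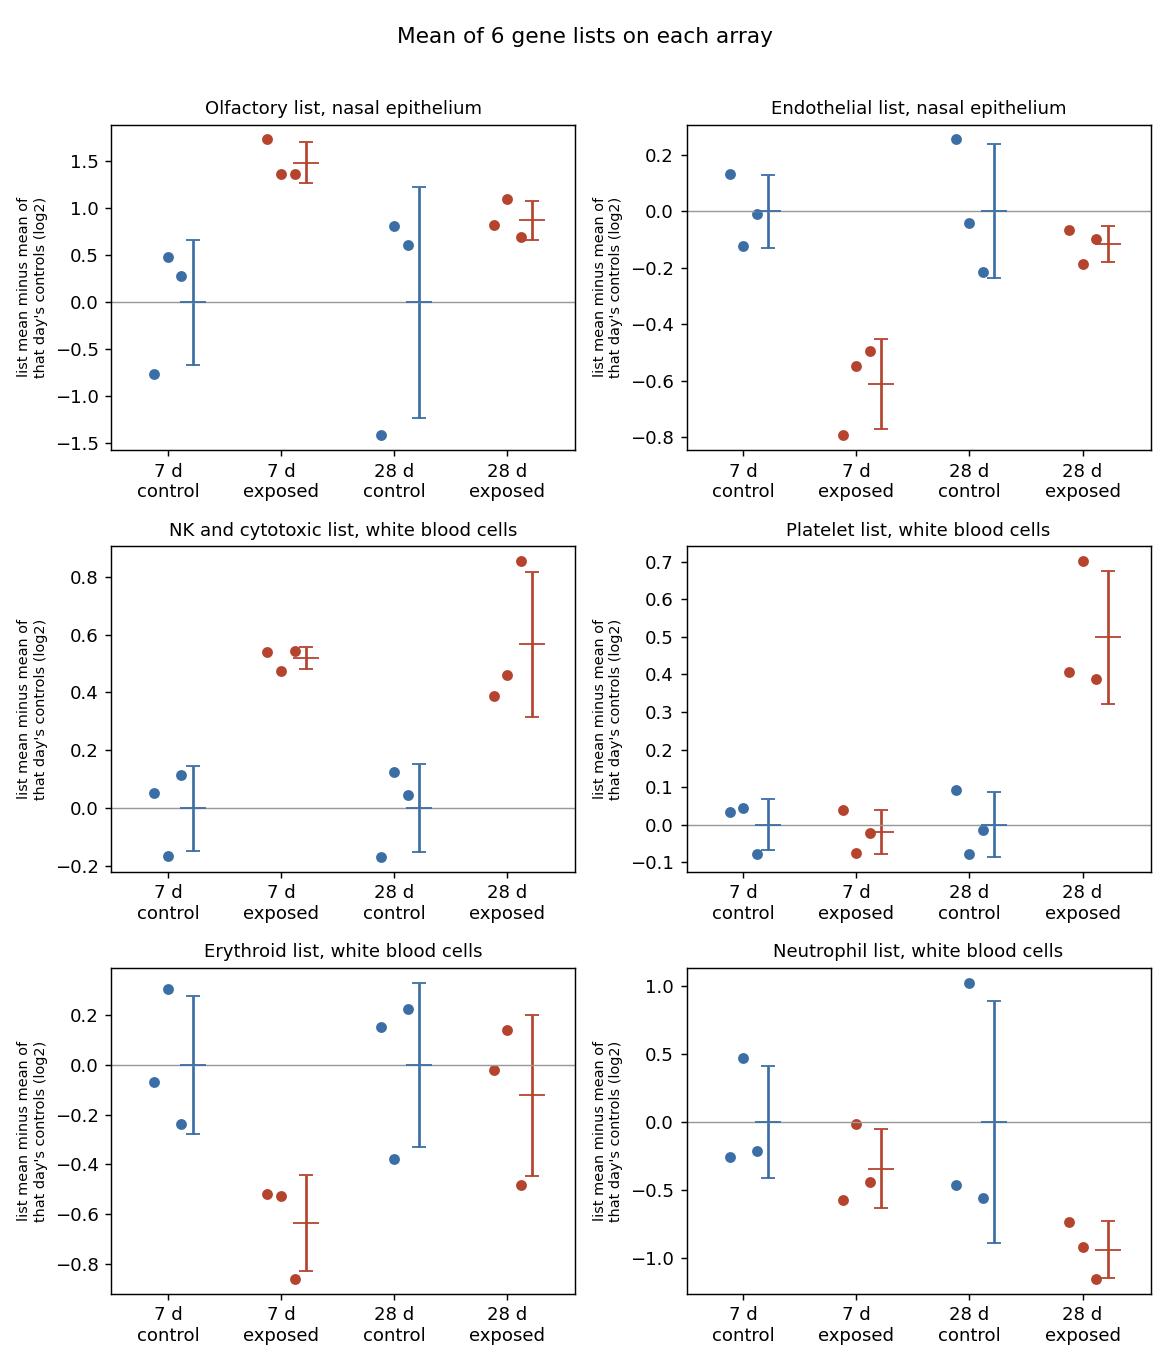
Mean log2 intensity of 6 gene lists on each array minus the mean of that day's control arrays; points are arrays and bars the mean ± SD of 3 arrays. The platelet list in blood at 28 days had an exposed mean of 0.50 ± 0.18, and the olfactory list in nose at 7 days 1.49 ± 0.21.

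After 28 days some cytotoxic genes were higher in blood, as were some platelet genes. Kir3dl1, a receptor of NK cells, rose by 1.66 ± 0.23, Klrc1, another NK receptor, by 1.24 ± 0.19, Klrg1 by 0.99 ± 0.14 and Gzmk by 0.91 ± 0.15. Of 32 NK and cytotoxic members 18 rose, 0 fell and 14 did not pass, and 24 rose adjusted over the list alone. The median was 0.52 and 31 of 32 members were above 0 (camera adjusted p = 2.22e-19, and adjusted p = 0.506 with an estimated correlation). Serpinb11, which belongs to the serpin protease inhibitors, stood at 10.73 ± 0.38 (SD, n = 3) in exposed and 9.25 ± 0.13 in control blood and rose by 1.48 ± 0.18. In the platelet list 14 of 19 rose, 0 fell and 5 did not pass, and 17 rose adjusted over the list alone. Plek, the platelet substrate pleckstrin, rose by 0.76 ± 0.10, the ADP receptor P2ry12 by 0.68 ± 0.11 and Ptgs1, the enzyme of thromboxane synthesis that aspirin blocks, by 0.66 ± 0.10. The platelet median was 0.49 (camera adjusted p = 2.25e-17, and adjusted p = 0.506 with an estimated correlation), and all 3 exposed arrays lay above all 3 control arrays in the list mean. The NK and platelet lists were also called by fry.

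Some genes of phagocytes and of resting T cells fell in blood at 28 days. Fn1, the matrix protein fibronectin, fell by 2.36 ± 0.59, the iron carrier gene Tf by 1.70 ± 0.37, the granule protein Ngp by 1.41 ± 0.31 (to an exposed level of 4.92, under the 5.96 of the filter in blood) and the lysosomal macrophage gene Cd68 by 1.19 ± 0.27. Camera called the neutrophil list lower (median −0.92), with Ngp and Chi3l1 lower and 26 of 28 not past, and the monocyte list (−0.33), with Cd68 and Csf2ra lower and 27 of 29 not past. Adjusted over the list alone 5 and 9 members fell. Of 31 immediate early genes 5 fell, 0 rose and 26 did not pass (12 fell adjusted over the list alone), among them Ier5 at −0.49 ± 0.09, Junb at −1.03 ± 0.23 and Nr4a1 at −1.10 ± 0.26. Of 29 T cell genes Lef1 (−0.52 ± 0.12), Tcf7 and Satb1, transcription factors of resting T cells, fell (4 fell adjusted over the list alone). The interferon list was called lower (median −0.21) although Cxcl10 (0.76) and Gbp2 (0.48), both induced by interferon, rose and only Bst2 (−0.44) fell of 37. The calls of Cxcl10 (0.52 to 0.96), Gbp2 (0.38 to 0.59) and Bst2 (−0.52 to −0.38) ended in 4, 3 and 4 of the 6 fits that left out an array. The lists of MHC class II (−0.31) and ribosomal proteins (−0.11) were called lower with 0 members past the threshold, and 1 and 0 lower adjusted over the list alone. With an estimated correlation the adjusted p values of these 7 lists were 0.874 to 0.943. The mean of the neutrophil list on control replicate 2 lay 1.02 above the mean of its group, and without that array the medians were −0.36 for neutrophils and −0.11 for immediate early genes. The MHC class II median was −0.19 without exposed replicate 2. Let-7 targets were not called, with Thbs1 higher of 30 and a median of −0.11, and Aldh2 (−0.58), Esd (0.02), Cat (−0.12) and Aldh3a1 (−0.013) did not pass (Aldh1a1 was not tested in blood).

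In blood at 28 days 866 probe sets rose and 288 fell, 75.0% higher, with 124 at least 2-fold. In the 38 named genes that passed the arrays did not overlap, where again the 10% of chance does not hold for genes chosen by passing. The count of 1154 was 623 without control replicate 3 and without exposed replicate 2. It was 1 in a fit of the 6 arrays of that day alone, in which each named gene lost its call. The count was 194, of which 13 were among the 1154, with the mean of the platelet list as a covariate, an alternative chosen after seeing the data. Each exposed array lay above each control array in that mean, so the covariate fit cannot tell the exposure from the list mean. Of the falls named, only that of Ier5 was past the threshold in every fit that left out an array, and Tf lost it without exposed replicate 2 (−1.46) or 3 (−1.62), Junb without exposed replicate 1 or 3, and Fn1 without any array but exposed replicate 1 (−1.79 to −2.66). The call of the T cell list ended without exposed replicate 2 (median −0.11) and the calls of the interferon (−0.085 and −0.14) and ribosomal lists (−0.049 and −0.022) without control replicate 3 or exposed replicate 2.

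The calls in blood at the 2 days overlapped. Of the 24 probe sets higher at 7 days 8 were higher at 28 days, against 0.949 expected (Fisher's exact test, p = 2.41e-06), and of the 80 lower 31 were lower, against 1.05 expected (Fisher's exact test, p = 7.50e-38). Genes are not independent replicates in these tests. In the interaction of exposure and day limma called 0 probe sets in blood, against 2528 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0605. The platelet list had a higher effect at 28 days (median 0.48, camera adjusted p = 2.40e-17, and adjusted p = 0.594 with an estimated correlation), with 0 members past the threshold and 15 higher adjusted over the list alone. The erythroid list had a higher effect (0.45), and the lists of monocytes (−0.66), ribosomal proteins (−0.25), T cells (−0.24) and interferon response (−0.23) a lower one. Fry called 0 of these 6 lists, and their adjusted p with an estimated correlation was 0.594 to 0.897. Across probe sets the effects at the 2 days correlated with r = 0.292 (exact permutation p = 0.20, Benjamini-Hochberg adjusted p = 0.6) and rho = 0.249 (exact permutation p = 0.25), with 55.4% of the same sign. Without 28 day exposed replicate 2 the r was 0.426 (exact permutation p = 0.02), and without 28 day exposed replicate 3 it was 0.150. Only the calls of the platelet, erythroid and ribosomal lists were past the threshold in every fit that left out an array. Without 28 day control replicate 2 the erythroid median was 0.22 and the call of the monocyte list ended.

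Control blood was compared between the days with the same limits as in nose, since array medians were 175 to 181 at 7 days and 113 to 119 at 28 days. The median difference of all genes was −0.69. Atp5mk (0.84 ± 0.12), Fignl1 (0.59 ± 0.11) and Or8i2 (0.50 ± 0.09, from a level of 5.77 under the filter) were higher at 28 days, and Klra17 (−1.95 ± 0.27), Blvrb (−1.84 ± 0.31), an enzyme of heme breakdown, and the IgE receptor gene Fcer2 (−1.78 ± 0.20) were lower by more than that shift. In total 86 probe sets were higher and 19406 lower, 0.441% higher, while quantile normalization gave 3202 higher and 2622 lower and median centring 4480 higher and 2427 lower. Camera called the lists of neutrophils (median −0.48), inflammatory cytokines (−0.43), type 2 response (−0.35) and monocytes (−0.63) higher than other genes although their medians and means were negative. With an estimated correlation the adjusted p values were 0.710 to 0.867.

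The last comparisons asked whether the exposure effect differed between nose and blood, as the effect in nose minus that in blood. At 7 days the olfactory receptors Or2l13 (3.32 ± 0.44), Or12j5 (3.27 ± 0.36) and Or12j3 (3.01 ± 0.43) had a higher effect in nose. Uts2r, the urotensin receptor gene (−2.22 ± 0.36), and Cxcr6, a chemokine receptor of T and NK cells (−2.06 ± 0.30), had a lower one. Akr1b8 (−1.83 ± 0.50) lost its call in 4 of the 12 fits that left out an array. In the list of NK and cytotoxic cells 10 of 18 members had a lower effect in nose (median −0.71), in that of endothelium 14 of 23 (−0.63) and in that of fibroblasts 8 (−0.32), while olfactory neurons had 5 of 15 higher (1.37). The lists of interferon response (−0.42), monocytes (−0.49), T cells (−0.30) and ribosomal proteins (−0.28) were lower and those of ciliated (0.18) and erythroid cells (0.24) higher. The calls of the ciliated, T cell, monocyte and erythroid lists ended without at least 1 array, and the interferon median was −0.28 without nose exposed replicate 1. With an estimated correlation the adjusted p values were 0.719 to 0.739. In total 1025 probe sets had a higher and 1136 a lower effect in nose among 20096. The count of 2161 was 822 without nose exposed replicate 1, 1000 without nose control replicate 1, 1172 without blood control replicate 2, 1363 without blood exposed replicate 2 and 1365 without blood exposed replicate 1. The effects in nose and blood correlated at r = 0.0061 (exact permutation p = 0.83, Benjamini-Hochberg adjusted p = 0.83) and rho = 0.023 (exact permutation p = 0.65), and 47.8% had the same sign. The r was −0.0117 without blood exposed replicate 3, −0.0096 without blood control replicate 3 and −0.0254 with no filter on dim probe sets. The calls in both tissues shared 1 higher probe set, against 1.49 expected, and 5 lower, against 5.87 expected.

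At 28 days Serpinb11 (−2.11 ± 0.28) and Kdelr3, a receptor of the secretory pathway (−1.95 ± 0.28), had a lower effect in nose than in blood, and Plxnb2 (1.56 ± 0.35) a higher one. Fn1 (2.45 ± 0.66), Tf (1.81 ± 0.43) and Serpinb10 (−2.75 ± 0.67) passed as well but lost their call in 7, 1 and 2 of the 12 fits that left out an array. The level of Serpinb10 in exposed nose, 6.33, lay under the 6.61 of the filter, so the size of its difference is uncertain. In the platelet list 10 of 17 members had a lower effect in nose (median −0.61, camera adjusted p = 3.28e-13, and adjusted p = 0.0870 with an estimated correlation) and in the NK list 8 of 18 (median −0.57, camera adjusted p = 1.42e-09, and adjusted p = 0.233 with an estimated correlation). The lists of basal cells (−0.31), mucous cells (−0.31) and bone (−0.14) were lower, and those of olfactory neurons (0.95), neutrophils (0.68), glucocorticoid response (0.41) and immediate early genes (0.32) were higher. With an estimated correlation their adjusted p values reached 0.841. Without nose control replicate 1 the calls of the olfactory (0.33), basal, mucous and bone lists ended, and without blood control replicate 2 those of the neutrophil (0.13), immediate early (0.089) and glucocorticoid lists (0.11). The bone, neutrophil and glucocorticoid calls ended without some other arrays too. In total 401 probe sets had a higher and 624 a lower effect, and 297 and 858 after median centring. The balance turned without nose control replicate 1 (1443 higher, 1124 lower) and without nose control replicate 2 (845 higher, 739 lower). The count of 1025 was 518, 682 and 603 without nose exposed replicate 1, 2 or 3, 627 without blood control replicate 3, 657 without blood exposed replicate 2, 1584 without nose control replicate 2 and 2567 without nose control replicate 1. With the replicate block it was 544, and Fn1, Tf and Plxnb2 lost their calls. The effects in nose and blood correlated at r = −0.0786 (exact permutation p = 0.46, Benjamini-Hochberg adjusted p = 0.613) and rho = −0.113 (exact permutation p = 0.45), with 45.5% of the same sign. Without nose control replicate 3 the r was 0.00063.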

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

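The exposure effect differed between days or between tissues by an interaction test in the results given here. The tests of a scale difference, of the amount of olfactory mucosa alone, of a lower share of another cell type and of the neutrophil-rich control array were chosen only after the result was seen. The comparisons, lists and rule for named genes were chosen before the data were examined.

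In nose at 7 days camera called the list of olfactory neurons higher, with 11 of 29 members past the threshold, and those of endothelium, with 18 of 25, and of immune cells lower, with from 2 of 16 neutrophil genes to 9 of 12 of MHC class II. The adjusted p with an estimated correlation was 0.402 for the olfactory list, 0.373 for endothelium and 0.323 to 0.402 for the lists of immune cells and MHC class II. Class II receptors differed by 0.60 more than class I receptors. A factor common to all genes of an array is argued against. The 7 day difference of the olfactory list exceeded that of the endothelium list by 2.16. The gap of their means was 1.90 to 2.56 on exposed arrays and −0.85 to 0.64 on control arrays. These lists were set against each other after their opposite signs were seen, so the gap restates the pattern. With each array centred on its median the olfactory median was still 1.49. The amount of olfactory mucosa alone stays open: slopes on the list mean within groups gave 0.352 of the class II difference, a value that reached from 0.276 to 0.432 without 1 array and was 0.728 for the 72 class II receptors at or above the median level. The class II receptors had a median level of 7.20, near the 6.61 of the filter, so low signal may limit their slopes. Why the brighter receptors differ was not tested. More olfactory mucosa in the exposed samples stays open too. Slopes of 21881 probe sets outside the list on its mean among 28 day arrays correlated with the 7 day effect at r = 0.613. Of the 10 splits of the 7 day arrays, the real one included, 4 gave an r as large in size (up to 0.669). Arrays that differ in mucosa would give a large r in other splits too, so the splits cannot decide this. The r was 0.301 without 28 day control replicate 1. Cyp2g1 and Stoml3, members of the list with the highest intensities, stood at 13.60 ± 0.09 and 13.61 ± 0.07 in exposed against 12.85 ± 0.66 and 12.43 ± 0.72 in control nose. Tissue from a different zone of the mucosa would give a gap between receptor classes like the 0.60 at 7 days. That gap cannot decide this, since the receptor set was formed after values of the same arrays were seen. A different zone and a larger amount of mucosa may act together. At 28 days the medians were 0.20 for class II and 0.27 for class I. The mean of the olfactory list varied without exposure, from 8.95 to 10.19 on control arrays at 7 days and from 7.41 to 9.63 at 28 days. On exposed arrays it was 11.07 to 11.44 at 7 days and 9.52 to 9.92 at 28 days. An effect of formaldehyde on the olfactory mucosa stays open and was not tested. Of the 29 members 15 were also measured in blood, and 2 belong to another list.

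In blood the NK and cytotoxic list was higher at both days, with medians of 0.51 and 0.52. Its adjusted p was 0.787 and 0.506 with an estimated correlation. A lower share of another cell type, which would raise every remaining type, is argued against at 7 days only. The list exceeded those of T cells, B cells and monocytes by at least 0.45 at both days. At 7 days the B cell list was itself called lower, so only the T cell and monocyte lists, not called then, bear on this. For 28 days the gap cannot decide, since the platelet list was higher too and the monocyte and T cell lists were themselves called lower. The neutrophil-rich control array at 28 days is argued against as the cause, since the NK median was 0.54 without it. More NK cells in the exposed blood and a higher level per cell stay open, and an effect of exposure may be held as a hypothesis that was not tested apart from the preparation of the samples. Of the 32 members 18 were also measured in nose and 0 belong to another list.

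In blood at 28 days the platelet list was higher, with a median of 0.49. Its adjusted p was 0.506 with an estimated correlation. The neutrophil-rich control array is argued against as the cause, since the median was 0.43 (0.425) without it. More platelets in the exposed preparations stay open. Slopes of 21891 probe sets outside the list on its mean correlated with the 28 day effect at r = 0.344. Of the 10 splits of the same arrays, the real one included, 5 gave an r as large in size (up to 0.669). Arrays that differ in platelets would give a large r in other splits too, so the splits cannot decide this. The r was 0.0456 without exposed replicate 2. F2rl2 and Gp1ba, members of the list with the highest intensities, stood at 12.81 ± 0.05 and 12.72 ± 0.07 in exposed against 12.39 ± 0.06 and 12.37 ± 0.05 in control blood. An effect of exposure on platelets themselves stays open, and the labels do not state how far the isolation of white cells removed platelets. Of the 19 members 17 were also measured in nose and 4 belong to another list.

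In nose the effect differed between days for 22 probe sets. Of the 12 with a gene name, those with the largest differences were Or4e5 (−5.39), Or4a15 (−4.15) and Or4k15c (−3.44). Their sizes are uncertain, and Or4e5 and Or4k15c lay under the filter in both groups at 28 days. The lists with a higher effect at 28 days were NRF2 and oxidative stress response (0.29), p53 targets (0.29), MHC class II presentation (0.31), endothelium (0.50), T cells (0.19), B cells (0.22), NK cells (0.13), erythroid cells (0.20), glucocorticoid response (0.24), circadian clock (0.46) and ribosomal proteins (0.14). Those with a lower effect were cell proliferation (−0.19), olfactory neurons (−0.57) and heat shock response (−0.061). With an estimated correlation 0 of these 14 calls held (adjusted p 0.716 to 0.831), and fry called 0. In blood the lists that differed between days were interferon response (−0.23), monocytes (−0.66), T cells (−0.24), platelets (0.48), erythroid cells (0.45) and ribosomal proteins (−0.25). With an estimated correlation 0 of these 6 held (adjusted p 0.594 to 0.897), and fry called 0.

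Between nose and blood 2161 probe sets differed in effect at 7 days and 1025 at 28 days. At 7 days 690 genes had a higher and 791 a lower effect in nose, and the 3 largest in each direction were Or2l13 (3.32), Or12j5 (3.27), Or12j3 (3.01), Uts2r (−2.22), Cxcr6 (−2.06) and Akr1b8 (−1.83). The lists at 7 days were interferon response (−0.42), ciliated cells (0.18), olfactory neurons (1.37), fibroblasts (−0.32), endothelium (−0.63), monocytes (−0.49), T cells (−0.30), NK cells (−0.71), erythroid cells (0.24) and ribosomal proteins (−0.28). None of these 10 calls held with an estimated correlation (adjusted p 0.719 to 0.739). At 28 days 252 genes had a higher and 450 a lower effect, and the 3 largest in each direction were Fn1 (2.45), Tf (1.81), Plxnb2 (1.56), Serpinb10 (−2.75), Serpinb11 (−2.11) and Kdelr3 (−1.95). The size and rank of Serpinb10 are uncertain, since its level in exposed nose lay under the filter. The lists at 28 days were basal cells (−0.31), mucous cells (−0.31), olfactory neurons (0.95), bone (−0.14), neutrophils (0.68), NK cells (−0.57), platelets (−0.61), immediate early genes (0.32) and glucocorticoid response (0.41). None of these 9 calls held with an estimated correlation (adjusted p 0.0870 to 0.841).

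Splits of the 6 arrays of an exposure comparison number 10 with the real one included, too few for a share under 0.05, since the smallest is 0.1. For probe sets past the threshold the real count and the highest of the others were 3564 and 0 in nose at 7 days, 1 and 0 in nose at 28 days, 104 and 0 in blood at 7 days, and 1154 and 5 in blood at 28 days. For 28 day against 7 day controls they were 20033 and 0 in nose and 19492 and 0 in blood. For called lists they were 22 and 25, 16 and 17, 11 and 13, and 9 and 20. In nose at 28 days, where the numbers may pair the arrays, the other 3 splits that part all 3 pairs gave 0 probe sets and 2, 11 and 15 lists. Those that part 1 pair gave 0 probe sets and 6 to 17 lists. For the differences between days and tissues 100 splits were drawn, the real one included. Chance cannot be excluded for the 22 probe sets and 14 lists that differed between days in nose, where 7 and 27 splits gave as many, with highest others of 3751 and 21. It cannot be excluded either for the 0 probe sets and 6 lists in blood, where 100 and 94 splits gave as many, with highest others of 1535 and 21. The splits that called 3751 and 1535 probe sets, many times the real counts, reflect a structure of the samples: they turn round the exposure labels of 1 day and keep those of the other, so they add the effects of the days. For the difference between tissues only the real split, 1 of 100, gave as many probe sets at either day. At 28 days the real count was 1025 and the highest other 456, but chance is not held as excluded. Blood alone had 1154 probe sets past the threshold and nose 1, so the effect in blood alone could carry much of the count. At 7 days chance is not held as excluded either, since the highest other, 2131, lies close to 2161. That split turns round the labels of blood and keeps those of nose, so the effect in nose alone could carry much of the count. Chance cannot be excluded for the 10 and 9 lists, where 75 splits gave as many at each day, with highest others of 22 and 21.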

How the results depend on the processing

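The mean of the olfactory list and the mean of the platelet list as covariates were chosen after seeing the data, and all other settings before. Over all settings, counts of probe sets or lists stayed within 1.5 times in 228 cases and moved further in 128. Correlations kept direction and side of the threshold in 67 cases, changed sign in 4 and came to pass in 1. Named genes and lists kept both in 5809 cases, lost the call in 1057, gained it in 172 and changed sign in 48. The cause was not tested where none is given. Low signal over background limits the dim probe sets, of which the filter removed those under percentile 25, and some receptors near that level could not be tested in every fit.

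With probe sets at or above the median, which tests fewer genes, the count was 2367 in nose at 7 days (13 lists), 0 in nose at 28 days (9 lists), 1 for the difference between days in nose (9 lists), 179 in blood at 7 days, 1 for the difference between days in blood and 1111 for the difference between tissues at 7 days (4 lists), with 3 lists at 28 days. With no filter on dim probe sets it was 145 for days in nose, 55 in blood at 7 days and 17 lists for tissues at 7 days, and the correlation between nose and blood at 7 days was −0.0254.

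The weights in nose and across tissues came from an estimation that stopped before it converged, so their values are uncertain. With array quality weights the count was 8640 and 0 in nose at 7 and 28 days, 0 for days in nose, 1380 and 533 in blood at 7 and 28 days, 2 for days in blood, and 6309 and 75 for tissues at 7 and 28 days. The signs changed for Esd (−0.072) and Aldh1a1 (−0.061) in nose at 28 days and Aldh3a1 (0.018) in blood at 28 days. With an intensity trend and robust prior it was 14 for days in nose and 1 for days in blood.

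With the replicate block the count was 1795 and 0 in nose at 7 and 28 days, 82 for days in nose, 2 and 392 in blood at 7 and 28 days, and 1414 and 544 for tissues at 7 and 28 days. Same-numbered arrays deviated together in nose at 28 days (r of 0.154 to 0.247, where 2 of 3 matched their own number best), and in no other 2 groups compared was every pair over 0.1. Under the block the call of the 1 probe set in nose at 28 days was lost, but no list call there. The replicate block does not apply to 28 day against 7 day controls.

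With only the arrays compared, which takes the spread from that day alone, the count was 6300 and 0 in nose and 463 and 1 in blood at 7 and 28 days. The largest SD of the difference between arrays of a group was 0.33 in control and 0.29 in exposed nose at 7 days, and 0.55 and 0.27 at 28 days. In blood it was 0.27 and 0.18 at 7 days and 0.32 and 0.33 at 28 days. A spread shared by the days can then be too large for 7 days and too small for 28 days. With all 24 arrays in the fit it was 385 in nose at 28 days, 471 for days in nose, 497 in blood at 7 days and 145 for days in blood.

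With the unadjusted screen the count was 1712 and 207 in nose at 7 and 28 days, 377 for days in nose, 244 and 649 in blood at 7 and 28 days, and 397 for days in blood. At adjusted p under 0.1, a looser threshold, it was 73 in nose at 28 days, 137 for days in nose, 537 and 1733 in blood at 7 and 28 days, 1 for days in blood, and 3509 and 1910 for tissues at 7 and 28 days.

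With quantile normalization the count was 42 in nose at 28 days, 1 for days in nose, 6517 and 5824 for 28 day against 7 day controls in nose and blood, and 264 in blood at 7 days, and Esd (−0.0088) and Cat (0.023) in nose at 28 days changed sign. With array median centring it was 13 for days in nose, 8263 and 6907 for controls in nose and blood, and 206 in blood at 7 days, and Esd in nose (−0.034) and Aldh3a1 in blood (0.017) at 28 days changed sign. Both scalings remove the shift between the days by construction.

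With the correlation estimated from the data the number of called lists was 0 in all 8 exposure and interaction comparisons. With fry it was 0 in nose at 28 days, for days in nose, in blood at 7 days and for days in blood, 2 in blood at 28 days, and 4 and 2 for tissues at 7 and 28 days.

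With the olfactory list mean as a covariate the count was 255 in nose at 7 days, 285 in nose at 28 days (7 lists) and 111 for days in nose. That mean was 11.07 to 11.44 on exposed and 8.95 to 10.19 on control arrays at 7 days. The groups did not overlap in it, so the 7 day fit cannot tell the exposure from the list mean. At 7 days Aldh2 (0.53) and Esd (0.22) changed sign and the basal cell list (−0.012) its direction, and at 28 days Cat (0.22), Aldh3a1 (0.13) and the endothelium list (0.074) changed sign.

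With the platelet list mean as a covariate the count in blood at 28 days was 194, with 13 of them among the 1154. Each exposed array lay above each control array in that mean, so this fit cannot tell the exposure from the list mean. The platelet list is adjusted for its own mean here, so its change is built in. The signs changed for C5ar1 (0.27), Chi3l1 (0.20), Plxnb2 (0.12), Lbp (0.11), Cd68 (0.090), Sirpa (0.15), Stat2 (0.22), RT1-DMa (0.17), RT1-DOb (−0.056), RT1-Bb (0.60), Cd74 (0.25), Csf2ra (0.058), Csf1r (0.36), Lyz2 (0.16), Rpl5 (0.052) and Aldh3a1 (0.15), and for the lists of interferon response (0.22), MHC class II (0.36), monocytes (0.16), platelets (−0.018) and ribosomal proteins (0.027).

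Leaving out each array in turn gave counts of 802 to 2658 in nose at 7 days, 0 to 1081 in nose at 28 days (6 to 19 lists), 1 to 2648 for days in nose (9 to 17 lists), 2 to 115 in blood at 7 days (5 to 11 lists), 623 to 1258 in blood at 28 days, 0 to 5 for days in blood, 822 to 2124 for tissues at 7 days and 518 to 2567 for tissues at 28 days (4 to 13 lists). Without exposed replicate 1 nose at 7 days gave 802, and without control replicate 1 nose at 28 days gave 1081. The correlation of days in nose was 0.0968 to 0.641, that of days in blood 0.150 to 0.426, and that of nose with blood −0.0117 to 0.0250 at 7 days and −0.128 to 0.00063 at 28 days. Esd ranged from −0.051 to 0.0091 in nose at 7 days, −0.16 to 0.15 in nose at 28 days and −0.062 to 0.12 in blood at 28 days. In nose at 28 days Cat was −0.18 to 0.21, Aldh1a1 −0.19 to 0.30, Aldh3a1 −0.29 to 0.075 and the endothelium list −0.23 to 0.025. Aldh3a1 in blood at 28 days was −0.066 to 0.028.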

Other observations

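The genes given here other than Nr1d1, which the rule names, were chosen only after their values were seen. The rule names Gstp1 in nose at 7 days but not in blood at 28 days, the comparison given here. The list of clock genes and its test were fixed before. In exposed nose at 7 days the clock genes Nr1d1 (−1.92 ± 0.28), Nr1d2 (−0.57), Dbp (−0.52), Bhlhe40 (−0.75) and Usp2 (−0.42) fell and Cry1 (0.58) rose, so 5 of 16 members fell, 1 rose and 10 did not pass. The list was not called at that day (median −0.23, camera adjusted p = 0.0815). In nose at 28 days 0 members passed over all genes, while adjusted over the list alone 5 were higher, among them Per2 (0.55), Per3 (0.49) and Tef (0.54), and 2 were lower, Bmal1 (−0.75) and Npas2 (−0.69). The time of day at which samples were taken is not stated in the labels.

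Some genes of lists that were not called passed the threshold in blood at 28 days. In the list of the NRF2 response Gsr (0.64), Gstp1 (0.66), Sod2 (0.67) and Me1 (0.91) rose and 0 of 26 fell, and the median was −0.0020. In the DNA repair list Rad18 (0.43) and Rpa2 (0.50) rose of 22. In nose at 7 days Muc1, a membrane mucin, fell by 1.09, and Folr1 (−1.29) and Aqp5 (−0.37), genes of nasal glands, fell as well.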
